A study of Mus musculus with 3 samples.

How the data were processed

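The libraries were made with the 10x Genomics 3' v3.1 chemistry, per the labels' protocols, from enzymatically dissociated lungs sorted live into gates of GFP and tdTomato. Reads were processed with Cell Ranger 7.0.0 against mm10, per the submitters' processing notes. The deposited matrix holds raw UMI counts per gene and cell for 31730 genes and 6142 cells, and the authors' table gives for each cell its gate, cell type, UMI and gene counts and the percent of mitochondrial UMIs. The sums of the matrix equalled the deposited counts per cell. The deposited cells hold 2504 to 7499 detected genes and at most 19.3% mitochondrial UMIs, so cells had been filtered, but no filter is given in the sources used here. How the cell types were called is not given either. The sequences H2BGFP, TDT and CreERT2 are listed as genes, and 30176 of the symbols matched GENCODE M21 on GRCm38, the build that mm10 names, from which coordinates were taken. A further sorted population, tdTomato-positive and GFP-negative, is not analysed here, and whether a library pools several pups is not given in the sources used here.

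All deposited cells were kept. UMIs were summed over the cells of a library and divided by the library's total to give counts per 1e6 UMIs (CPM), and genes were compared as the log2 ratio of CPM plus a pseudocount of 1. Each sum has an exact Poisson interval, each ratio an exact conditional binomial interval and each share of cells an exact Clopper-Pearson interval, all at 95% and covering counting error only. A count of 0 allows up to 3 counts, which is 0.113, 0.0437 and 0.0869 CPM in the GFP-low tdT-negative, GFP-high tdT-negative and GFP-high tdT-high libraries. No test was run and no p-value was computed, because each gate has 1 library. Named genes were the 12 highest and 12 lowest log2 ratios among genes with at least 50 CPM and a UMI in at least 10% of cells of the higher library, leaving out mitochondrial, ribosomal protein, haemoglobin, sex-linked and unnamed genes. A fixed set of reporter and marker genes was always given, together with members of each list chosen by level or ratio. Within a type, which needed 100 cells in both libraries, the 5 highest and 5 lowest were named. The rule, the 28 gene lists and 13 marker lists were fixed before the data were examined. A list member needed 10 UMIs in either library, a member was counted as higher or lower from 1.5-fold, and the list's median was placed among 10000 random lists matched on expression in 20 bins, as a description of these libraries. Intervals of list medians came from 1000 Poisson draws. Under the alternatives the members were those of all cells, except within a type, where a member needed 10 UMIs in that type. Shares of cells with a UMI were computed on cells thinned to 5000 UMIs, which every cell reached, and on all UMIs.

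The calculation was tested on simulated data, with 200 genes changed by known folds, and gave for GFP-high tdT-negative over GFP-low tdT-negative the following. All 65 genes set to change 4-fold passed 2-fold, 23 of 66 genes set to change 2-fold did, and 0 of the 3649 unchanged genes did. Totals were rescaled after the folds were set. The interval held the true ratio for 95.0% of the unchanged genes, and for 87.9% to 98.5% of genes over all folds and comparisons. The simulated counts held Poisson error only, which the interval assumes, so this coverage says nothing about variation between cells, animals or libraries. Work was done with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scanpy 1.11.5. Alternatives planned beforehand were TMM scaling (edgeR 4.0.16), median-of-ratios size factors (DESeq2 1.42.0), the mean of each cell's CPM, a pseudocount of 5, a minimum of 10 CPM or none, stricter cell filters, doublet removal with Scrublet, removal of DivFB cells, thinned UMIs, totals without mitochondrial, ribosomal and haemoglobin genes, the most frequent shared type, and Leiden clusters of the cells at resolution 1.0 and 2.0. TMM moved the median log2 ratio of the counted genes from 0.18 to 0.051 in GFP-high tdT-negative over GFP-low tdT-negative and from 0.11 to -0.022 in GFP-high tdT-high over GFP-low tdT-negative, and all ratios in the report are without this shift. Scrublet marked 4 of 6142 cells, too few to count as a working doublet call, so doublets were not removed and this alternative was dropped. Alternatives chosen after the data were seen kept only cells with Y-linked UMIs, kept only cells with Xist UMIs, weighted the types of the GFP-high tdT-negative library to those of the GFP-high tdT-high library, or left out of AdvFB, MyoFB-Ter and MatFB-Im,Cuff the cells that formed a separate cluster at resolution 1.0, or kept only those cells of MatFB-Im,Cuff. In AdvFB only a cluster of GFP-low cells was left out, and 16 GFP-high tdT-negative AdvFB cells in another cluster of their own were kept.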

Results

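Single-cell RNA sequencing was carried out on lung mesenchyme of mouse pups at postnatal day 7. The pups carried a tamoxifen-inducible Cre recombinase at the Fgf18 locus (Fgf18-CreERT2), a Cre-dependent tdTomato reporter at the ROSA locus, and a green fluorescent reporter at the Pdgfra locus, and received tamoxifen from postnatal day 2 to day 5. Cells were sorted by flow cytometry into 3 gates, and each gate gave 1 droplet library: GFP-low tdT-negative (1284 cells, 26586489 UMIs), GFP-high tdT-negative (3347 cells, 68692834 UMIs) and GFP-high tdT-high (1511 cells, 34506226 UMIs). The median cell held 19798.5, 19629 and 22401 UMIs in that order, with a median mitochondrial share of 3.46%, 2.65% and 3.38%. Ribosomal protein genes took 9.41%, 9.62% and 7.77% of the UMIs. With 1 library per gate there is no replicate, no test was possible and no difference below has a replicate check. Intervals are exact 95% intervals of the counts and cover counting error only, so they say nothing about the spread between animals or sorts.

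The tdTomato transcript was highest in the gate sorted for it, and over all cells the GFP transcript was higher in both GFP-high gates than in the GFP-low gate. The tdTomato transcript stood at 2.67 CPM in the GFP-low tdT-negative library, 4.31 CPM in the GFP-high tdT-negative library and 60.0 CPM in the GFP-high tdT-high library. It was seen in 61.9% of GFP-high tdT-high cells (95% interval 59.4 to 64.3), against 6.75% (5.93 to 7.66) and 4.91% (3.79 to 6.23) in the GFP-high and GFP-low libraries sorted as tdT-negative, where its source was not tested. After thinning every cell to 5000 UMIs these shares were 23.6%, 1.85% and 1.09%. Fgf18, a fibroblast growth factor gene (chromosome 11, 33117430 to 33147400, GRCm38), stood at 4.48, 51.4 and 86.3 CPM in the GFP-low, GFP-high tdT-negative and GFP-high tdT-high libraries, and the CreERT2 transcript at 1.28, 17.0 and 27.7 CPM. Pdgfra, the platelet-derived growth factor receptor alpha gene (chromosome 5, 75152292 to 75198215), was highest in the GFP-high tdT-negative library, at 457 CPM against 167 CPM in GFP-low and 342 CPM in GFP-high tdT-high cells. The transcript of the reporter, H2BGFP, had the same order, at 56.0, 209 and 137 CPM. In the deposited MyoFB types alone, H2BGFP was seen after thinning in 37.9% (26.2 to 50.7) of 66 GFP-low cells. It was seen in 59.9% (58.0 to 61.7) of GFP-high tdT-negative and 37.1% (34.6 to 39.6) of GFP-high tdT-high MyoFB cells.

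The deposited annotation names 10 cell types, whose abbreviations are used here as given. MyoFB types made up 5.14% of the GFP-low tdT-negative cells (95% interval 4.00 to 6.49), 79.4% of the GFP-high tdT-negative cells (78.0 to 80.8) and 96.5% of the GFP-high tdT-high cells (95.4 to 97.4). MatFB types went the other way, at 82.2% (80.0 to 84.2), 5.08% (4.36 to 5.88) and 0.463% (0.186 to 0.952). AdvFB cells held 11.5%, 9.80% and 0.265% of the libraries, the last being 4 of 1511 cells. Dividing cells (the DivFB types) were most frequent in the GFP-high tdT-negative library, at 5.68% (4.92 to 6.52) against 1.17% (0.655 to 1.92) in GFP-low and 2.78% (2.01 to 3.74) in GFP-high tdT-high cells. Within the GFP-high gates, MyoFB-IMR held 30.8% of tdT-negative and 30.9% of tdT-high cells, MyoFB-Int 39.6% of the tdT-negative and 801 of the 1511 tdT-high cells, and MyoFB-Ter 9.05% and 12.6%. All of these shares are set in part by the sort gates.

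**Figure D1:**
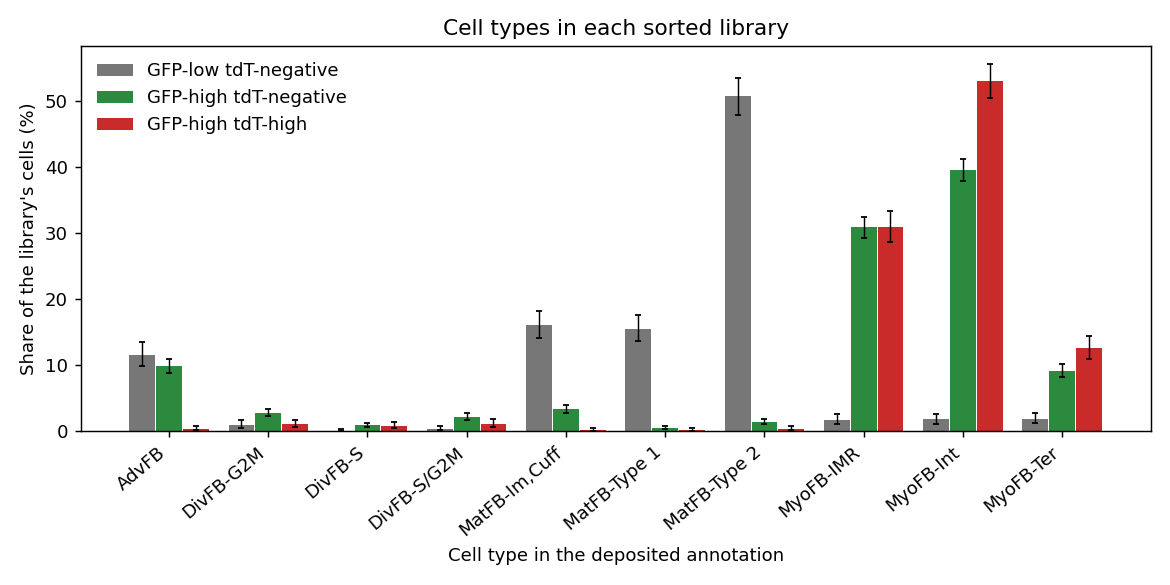
Share of each library's cells, in percent, that the deposited annotation assigns to each of 10 cell types, with exact 95% binomial intervals; bars are coloured by sorted library. MatFB-Type 2 holds 50.7% of the GFP-low tdT-negative library, and MyoFB-Int 39.6% of the GFP-high tdT-negative library and 801 of the 1511 cells of the GFP-high tdT-high library.

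The first comparison asked how cells with a high Pdgfra reporter differ from cells with a low one when neither carries the Fgf18-CreERT2 label. Summed over all cells, the GFP-high tdT-negative library had more of the contractile genes Acta2 (1123 against 384 CPM, a ratio of 2.92, 95% interval 2.86 to 2.98) and Tagln (1386 against 361 CPM, 3.84-fold), and more Pdgfra (2.73-fold). In MyoFB cells alone (66 GFP-low and 2659 GFP-high tdT-negative), 84.8% (73.9 to 92.5) and 84.7% (83.2 to 86.0) held an Acta2 UMI after thinning. For Pdgfra these shares were 42.4% (30.3 to 55.2) and 79.5% (77.9 to 81.0). The largest ratios among abundant genes were those of Rbfox1, a splicing regulator (1733 against 54.2 CPM, 32.0-fold, 30.3 to 33.7), and Egfem1 (9092 against 328 CPM, 27.7-fold, 27.1 to 28.3). Zfp536, Nrxn3, Csmd1, P2ry14 (a receptor for UDP-sugars), Nes (nestin, an intermediate filament), Htra1 (a secreted serine protease), Vsnl1, Trpc6, Trim67 and Ccdc3 completed the 12 highest, between 19.2-fold and 24.0-fold. The lowest were led by the carboxylesterase gene Ces1d (0.873 against 131 CPM, 151-fold lower, 117 to 198), the amino acid transporter gene Slc7a10 (65.1-fold lower), Mettl21e (57.1-fold), Ctnnd2 (54.6-fold), Nebl (49.9-fold) and the Wnt ligand gene Wnt2 (45.4-fold). Prkg2, Hsd11b1 (which activates glucocorticoids), the fatty acid transporter gene Slc27a6, Npnt (an integrin ligand of the matrix), Cpm and Scube2 were between 28.6-fold and 44.3-fold lower. Tcf21, a transcription factor gene (chromosome 10, 22817281 to 22820174), was 15.6-fold lower, and Plin2, which coats lipid droplets, 4.69-fold lower. Eln, the tropoelastin gene (chromosome 5, 134702593 to 134747323), did not differ, with 5578 against 5569 CPM. Hhip, an inhibitor of hedgehog ligands, was 2.89-fold lower.

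By the lists fixed beforehand, all 17 alveolar fibroblast markers were at least 1.5-fold lower in the GFP-high tdT-negative library, with a median log2 ratio of -3.94 (counting interval -3.99 to -3.89), below all 10000 random lists of matched expression. Limch1 stood at 142 against 3398 CPM and Mfap4 at 573 against 6680 CPM. Of 12 myofibroblast markers 10 were higher and 1 lower, with a median of 1.62, and Tgfbi stood at 1544 against 105 CPM and Stc1 at 80.4 against 5.98 CPM. Of 25 genes of the contractile apparatus 15 were higher and 5 lower (median 1.03), and Myh11, a smooth muscle myosin gene, stood at 654 against 136 CPM. Of 50 genes of the G2 and M phases 39 were higher and 1 lower (median 1.46), with Mki67 at 61.2 against 11.1 CPM, and 17 of 33 S phase genes were higher with none lower. DivFB cells moved with these lists, at 5.68% against 1.17%. The lipid list had 12 of 27 measured genes lower and 3 higher (median -0.38), with Apoe at 297 against 938 CPM and G0s2 at 49.6 against 569 CPM. The Notch list had 8 of 15 lower and 1 higher (median -0.59), and the vascular and guidance list 8 of 17 lower and 5 higher, among them Slit2 at 140 against 2958 CPM and Sema3c at 318 against 51.2 CPM. The TGF-beta and BMP list had 13 of 29 higher and 3 lower (median 0.55), and the Wnt list 12 of 28 higher and 7 lower, with Lef1 at 166 against 10.8 CPM and Wnt5a at 421 against 129 CPM. Collagens were near even, with a median of 0.073 that became -0.046 with TMM and -0.047 with DESeq2 scaling. The epithelial, endothelial and immune marker lists had medians of -0.19, 0.14 and 0.13.

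Of 4017 genes with at least 50 CPM and a UMI in at least 10% of cells of the higher library, 422 were at least 2-fold higher and 356 at least 2-fold lower in these libraries. The balance depended on the scaling, with 355 higher and 401 lower under both TMM and DESeq2 size factors. Only AdvFB and MatFB-Im,Cuff had 100 cells in both libraries. Within AdvFB the contractile genes turned round: Acta2 stood at 35.0 CPM in 328 GFP-high tdT-negative cells against 1485 CPM in 148 GFP-low cells, Tagln at 26.8 against 1119 CPM, and all 11 measured smooth muscle markers were lower, with a median of -4.12. Grp was 145-fold and Erbb4 51.7-fold lower. At a clustering resolution of 1.0, though not at 0.5, 55 of the 148 GFP-low AdvFB cells formed a separate cluster, which carried most of these values, with 4084 CPM of Acta2 against 63.0 CPM in the other 93. Against those 93 cells, a comparison chosen after the data were seen, Acta2 was 1.80-fold lower (1.47 to 2.20), Tagln 1.54-fold and Grp 8.98-fold lower in the GFP-high tdT-negative library. Erbb4 (6.08 against 2.52 CPM), Myh11 (17.0 against 2.94 CPM), Actg2 (6.08 against 2.10 CPM) and Des (11.9 against 2.52 CPM) were higher there, and of 10 smooth muscle markers 4 were higher and 3 lower, with a median of -0.19 (-0.35 to 0.29). The counting intervals of the 2 levels overlapped for Erbb4 (4.52 to 8.02 against 0.925 to 5.49 CPM) and Actg2 (4.52 to 8.02 against 0.682 to 4.90 CPM). At such low levels, free RNA from other cells of the GFP-high tdT-negative library was not ruled out as the source of these genes. Kept in the comparison with the 93 cells were 16 GFP-high tdT-negative AdvFB cells, which formed a cluster with 0 GFP-low cells at 0.5, 1.0 and 2.0. It is therefore not wholly between like cells. Of the 120 higher and 155 lower genes within AdvFB, 54 and 19 remained without the separate cluster. Nes, Htra1 and Ccdc3, named above as higher, were lower within AdvFB, of which Ccdc3 stayed lower without that cluster (3.30-fold). Zfp536, Trim67, Prkg2, Wnt2 and Scube2 did not differ there beyond counting error. Adventitial fibroblast markers had 12 of 14 higher and none lower within AdvFB (median 1.10, 1.05 to 1.16), and 7 higher and none lower without the separate cluster (median 0.60). Markers of other cell types moved there too: all 3 measured mesothelial markers were higher (median 1.62, and 1.25 without the separate cluster), as were 3 of 5 endothelial markers, with 1 lower (0.94, and 0.43 without it), and 4 of 5 erythroid markers (0.85, and 1.04 without it), while 1 of 3 epithelial markers was higher and 2 lower (-1.13, and -0.96 without it). These rest on low counts: over AdvFB cells of all libraries, 1 of 10 mesothelial, 3 of 12 endothelial, 2 of 7 erythroid and 2 of 14 epithelial markers reached 10 CPM. Pericyte markers had 7 of 12 lower and 2 higher within AdvFB (median -1.09, -1.21 to -0.97). The TGF-beta and BMP list turned, with 5 of 29 higher and 8 lower within AdvFB (median -0.28, and -0.059 without the separate cluster), and so did myofibroblast markers, with 2 of 12 higher and 6 lower (median -0.33, and 0.15 without it). Alveolar fibroblast markers (4 of 17 higher and 6 lower, median 0.20, interval -0.10 to 0.28, and -0.14 without the separate cluster) and the lipid list (5 of 23 higher and 5 lower, median 0.16, -0.024 to 0.30) were near even there. The vascular and guidance list had 7 of 17 higher and 3 lower in AdvFB (median 0.41) and 6 higher and 4 lower in MatFB-Im,Cuff (median 0.20). Within MatFB-Im,Cuff, the contractile apparatus had 8 of 24 genes lower and 6 higher (median -0.33) and the G2 and M phases 12 of 29 lower and 4 higher (median -0.42), both against their direction in all cells. In that type, 13 of 17 alveolar fibroblast markers were lower and none higher in the GFP-high tdT-negative library (median -1.39), 10 of 13 adventitial fibroblast markers were higher and 1 lower (median 1.41), Eln was 1.98-fold higher (1.95 to 2.02) and 13 of 21 elastic fibre genes and 11 of 13 measured genes of the PDGF and IGF pathways were higher. The 2 libraries filled different clusters under this name: at a resolution of 1.0, cluster 14 held 93 of the 110 GFP-high tdT-negative but 18 of the 205 GFP-low cells, and cluster 0 held 7 and 154 of them. At 0.5 and at 2.0 a cluster with 98 and 18 of these cells was found. Among the 93 and 18 cells of cluster 14, a comparison chosen after the data were seen, Eln was 1.18-fold higher (1.14 to 1.22), the medians of alveolar and adventitial fibroblast markers were 0.37 and 0.35, those of the contractile apparatus and of the G2 and M phases 0.097 and 0.67, and 1 of 20 elastic fibre genes (median 0.18) and 2 of 13 genes of the PDGF and IGF pathways (0.13) were higher. Of the other 17 GFP-high tdT-negative cells, 10 lay in cluster 2, named adventitial fibroblast-like by its markers, which held 0 of the 205 GFP-low cells. The other 187 GFP-low cells lay in clusters 0 and 1, named alveolar fibroblast-like, so in part unlike cells are compared here. Among these 17 and 187 cells, Eln was 2.00-fold lower (1.87 to 2.14), but 11 of 20 elastic fibre genes were higher and 3 lower (median 0.77), and 8 of 11 genes of the PDGF and IGF pathways were higher and none lower (1.21). The medians of alveolar and adventitial fibroblast markers were -1.38 and 1.45 there, and those of the contractile apparatus and of the G2 and M phases -0.23 and -0.25, with intervals that spanned 0. The immediate early and dissociation response had 16 of 23 genes higher and none lower inside cluster 14 (median 0.88, 0.70 to 1.06) and 15 of 24 higher and 1 lower outside it (0.71), against 6 of 25 higher and 2 lower in all cells of the type (0.17). Egfem1 was among the highest genes within both types, at 139 against 1.90 CPM in AdvFB and 344 against 5.45 CPM in MatFB-Im,Cuff. These levels are 1.24% and 3.07% of that in the MyoFB cells of the same library, so that free RNA from MyoFB cells was not ruled out as their source.

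The second comparison asked how cells labelled through Fgf18-CreERT2 differ from unlabelled cells of the same GFP-high gate. GFP-high tdT-high cells had 2.17 times the Eln of GFP-high tdT-negative cells (12128 against 5578 CPM, interval 2.16 to 2.18), 4.95 times the Aspn, a small matrix proteoglycan (1727 against 349 CPM, 4.88 to 5.03; chromosome 13, 49544443 to 49567565), 2.78 times the Hhip (374 against 134 CPM) and 1.68 times the Fgf18 (1.60 to 1.76). After tdTomato (13.9-fold), the highest ratio was that of Gt(ROSA)26Sor, the transcript of the reporter locus, at 79.8 against 8.53 CPM. Rgs5, a regulator of G protein signalling, was 8.35-fold higher, Mpped2 6.30-fold, Gja1 (a gap junction protein) 5.92-fold, Fhod3 4.53-fold, the potassium channel gene Kcnq5 4.30-fold, the calcium channel subunit gene Cacna2d3 3.88-fold and Fat3 3.71-fold higher. Cdk8 (4729 against 1267 CPM) and 7SK.197 (443 against 104 CPM) were also among the 12 highest, but the GFP-low library held 4337 and 558 CPM of them, so that the GFP-high tdT-negative library stood apart. Acta2 was lower, at 922 against 1123 CPM, and Tagln close to even, at 1333 against 1386 CPM, with the opposite sign among cells with Xist UMIs (log2 ratio 0.099).

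The lowest genes included Abca8a (3.39 against 152 CPM, 44.8-fold lower, 37.4 to 54.3), the collagen-binding proteoglycan gene Dcn (33.9-fold) and Serpinf1 (33.6-fold). Gpc3, Ebf1, Pid1, Clec3b, Lum, Itm2a, Dpep1 and Efna5 were between 11.6-fold and 27.9-fold lower. All 14 adventitial fibroblast markers were lower, with a median of -2.61, and so were 14 of 17 alveolar fibroblast markers (median -1.04). Of 50 G2 and M phase genes 36 were lower and none higher (median -0.91), with Mki67 at 34.5 against 61.2 CPM. The collagen list had 8 of 21 lower, including Col1a1 at 1281 against 3006 CPM, and 1 higher, Col12a1, at 256 against 90.6 CPM. Smooth muscle markers had 5 of 12 higher and none lower (median 0.34), among them Myocd, a coactivator of contractile genes, at 137 against 69.6 CPM. Within MyoFB-IMR, MyoFB-Int and MyoFB-Ter that median was 0.14, -0.054 and 0.80, the last becoming 0.017 (-0.11 to 0.26), with 1 of 11 markers higher, outside a separate cluster described below. The shares of AdvFB, MatFB and DivFB cells moved with these lists, at 0.265% against 9.80%, 0.463% against 5.08% and 2.78% against 5.68%. Of 3798 genes, 45 were at least 2-fold higher and 59 at least 2-fold lower. When the types of the GFP-high tdT-negative library were weighted to the make-up of the GFP-high tdT-high library, an alternative chosen after the data were seen, 46 genes were higher, 32 of them among the 45, and 1 gene was lower, which was not among the 59. With this weighting the adventitial and alveolar fibroblast lists had medians of -0.038 and -0.033, and Lum, Itm2a and Wnt2 were higher rather than lower.

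Within each MyoFB type, the matrix genes Eln and Aspn were higher in the GFP-high tdT-high library. Eln was 2.01-fold higher in MyoFB-IMR (6507 against 3239 CPM), 2.20-fold in MyoFB-Int (15714 against 7131 CPM) and 1.35-fold in MyoFB-Ter (14245 against 10556 CPM). Aspn was 6.85-fold, 6.23-fold and 4.26-fold higher in that order, and Hhip 1.89-fold, 3.28-fold and 4.60-fold. Elastic fibre genes, of which 2 of 21 were higher and 8 lower in all cells, had 6 of 20 higher and none lower in MyoFB-IMR, 7 of 20 higher and 1 lower in MyoFB-Int, and 5 of 18 higher and 1 lower in MyoFB-Ter. Collagens had a median of -0.27 in all cells, and of 0.29, 0.27 and 0.48 in MyoFB-IMR, MyoFB-Int and MyoFB-Ter. The libraries filled the clusters of MyoFB-Int unevenly: at a resolution of 1.0, cluster 7 held 357 of the 801 GFP-high tdT-high and 88 of the 1324 GFP-high tdT-negative cells, and cluster 8 held 54 and 328. In MyoFB-Int, Acta2 was 1.73-fold lower, and the lowest genes were the mechanosensitive channel gene Piezo2 (3.67-fold), Tafa1 (3.05-fold), Zmat4 (2.93-fold), Cygb (2.39-fold) and Cd34 (2.36-fold). MyoFB-IMR had 11 genes at least 2-fold higher and 0 lower, MyoFB-Int 50 and 15, and MyoFB-Ter 144 and 97. In MyoFB-Ter, Kcnq5 was 49.0-fold higher (37.1 to 66.1), though it was lower in MyoFB-IMR (3.65 against 6.48 CPM), and other leading genes were Otof (41.9-fold), Adamts19 (26.7-fold), Pcdh15 (16.4-fold) and Lrrc15 (14.1-fold), while Vsnl1 was 17.7-fold and Cd34 15.1-fold lower. Pdgfra was 8.51-fold lower there (24.6 against 209 CPM, 6.89 to 10.6) and H2BGFP 11.1-fold lower (7.51 against 83.4 CPM), although both libraries came from the GFP-high gate. Of the MyoFB-Ter cells, 139 of 190 GFP-high tdT-high, 5 of 303 GFP-high tdT-negative and 23 of 23 GFP-low tdT-negative cells lay in a cluster of their own. The marker lists named this cluster smooth muscle-like at resolutions of 0.5, 1.0 and 2.0. At 1.0, its 23 unlabelled GFP-low cells held 1743 CPM of Kcnq5 and 3097 CPM of Hhip. Its 139 GFP-high tdT-high cells held less, at 632 and 1736 CPM. Outside that cluster, a comparison of 51 with 298 cells chosen after the data were seen, Pdgfra was 3.56-fold lower (59.9 against 213 CPM, 2.74 to 4.71) and H2BGFP 4.65-fold lower (18.3 against 85.0 CPM) in the GFP-high tdT-high library. Kcnq5 turned round, with 632 CPM in the tdT-high cells of the cluster and 0 UMIs in the other 51, which allows up to 3.05 CPM, against 9.40 CPM in the 298. There Otof was 10.1-fold, Lrrc15 11.9-fold, Pcdh15 2.19-fold, Hhip 2.26-fold and Eln 1.98-fold higher, Adamts19 did not differ beyond counting error, and Vsnl1 was 8.85-fold and Cd34 9.43-fold lower. Of the 144 higher and 97 lower genes within MyoFB-Ter, 77 and 54 remained. The immediate early and dissociation response had 14 of 25 genes higher and none lower outside the cluster (median 0.70, 0.60 to 0.84), against a median of 0.17 in all MyoFB-Ter cells.

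**Figure D2:**
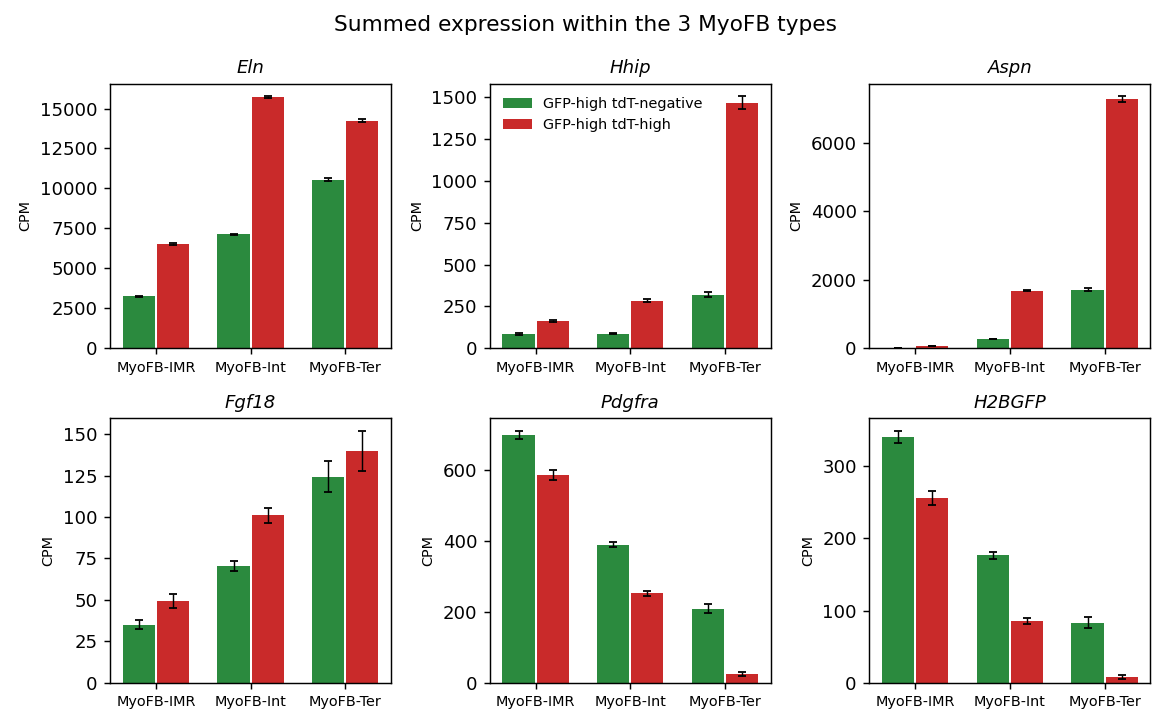
Summed expression in CPM of 6 genes within the 3 MyoFB types, for the GFP-high tdT-negative and the GFP-high tdT-high library, with exact 95% Poisson intervals. Eln and Aspn are higher in the tdT-high library in each type, while Pdgfra in MyoFB-Ter is at 24.6 CPM against 209 CPM in the tdT-negative library.

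The third comparison, GFP-high tdT-high over GFP-low tdT-negative, shares its libraries with the others and differs in both reporters. Of 4004 genes, 441 were at least 2-fold higher and 414 at least 2-fold lower, against 396 and 479 with TMM and 392 and 484 with DESeq2 size factors, so that the balance turned with the scaling. The 12 highest were Prkcq, a protein kinase C gene (103 against 2.03 CPM, 50.8-fold, 38.8 to 67.7), Rbfox1 (33.3-fold), Egfem1 (26.1-fold), Trim67, Nrxn3, P2ry14, Zfp536, Pappa2, Csmd1, Ccdc3, Tgfbi and Cacna2d3. The lowest included Ces1d (567-fold lower, 288 to 1315, from 0.232 CPM), the complement gene C7 (261-fold), Slc36a2 (0.898 against 177 CPM), Npnt (193-fold), Ablim3 (181-fold), Amph (163-fold), Meox2 (153-fold), Rapgef5 (150-fold), Nebl (146-fold), Maf (138-fold), Hsd11b1 (133-fold) and the integrin gene Itga8 (118-fold). Of 12 myofibroblast markers 11 were higher (median 2.53), all 17 alveolar fibroblast markers were lower (median -5.76), and 9 of 16 genes of retinoid metabolism were lower and 2 higher (median -1.24).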

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

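The tests of the range of Cdk8 over cell types, of Cdk8 in unlabelled MyoFB cells, of free Acta2 RNA and of cells from outside the gate were chosen after the result was seen. So was the reading that leaves a shift within MyoFB-Ter open.

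Eln stood out because types moved in opposite directions in GFP-high tdT-negative over GFP-low tdT-negative: its log2 ratio was 0.99 in MatFB-Im,Cuff and -1.39 in AdvFB, a difference of 2.38 that was not tested. Without the separate cluster of GFP-low AdvFB cells the value in AdvFB was -0.81. MatFB-Im,Cuff lay in different clusters in the 2 libraries, cluster 14 at a resolution of 1.0 holding 93 of 110 GFP-high tdT-negative and 18 of 205 GFP-low cells: Eln was 1.18-fold higher inside that cluster and 2.00-fold lower outside it, a split chosen after the data were seen, so the opposite direction was not kept in every part of the type. Outside it, 10 of the 17 GFP-high tdT-negative cells lay in an adventitial fibroblast-like cluster that held 0 of the 205 GFP-low cells, so in part unlike cells are compared there. Sex-linked transcripts, which no comparison uses, gave a signal in every library. Xist UMIs without Y-linked UMIs were found in 37.0% of GFP-low tdT-negative, 22.2% of GFP-high tdT-negative and 21.6% of GFP-high tdT-high cells, and Y-linked UMIs without Xist UMIs in 50.7%, 61.5% and 64.0%.

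Cdk8 and 7SK.197 were higher in the GFP-high tdT-high than in the GFP-high tdT-negative library in each MyoFB type, Cdk8 by 3.43-fold, 3.60-fold and 4.04-fold in MyoFB-IMR, MyoFB-Int and MyoFB-Ter. The tables argue against expression that follows the cell type, since the log2 ratio of Cdk8 ranged by 0.23 over these types and the pooled DivFB types, and against cells of 1 sex, since it differed by 0.083 between cells with Y-linked and with Xist UMIs. They also argue against the Fgf18-CreERT2 label, the biological explanation that the gates offer, as needed for the higher level, since unlabelled GFP-low cells lay at least 1.68 (log2, 95% interval 1.62 to 1.74) above GFP-high tdT-negative cells in each MyoFB type, from 21, 22 and 23 GFP-low cells. A difference between the libraries in reads of ribosomal or other structural RNA stays open: within MyoFB-Int, 8 genes known to draw such reads had a median log2 ratio of 0.61, between the bounds set for and against it, with Cmss1 at 1.08, Lars2 at 1.00 and Zc3h7a at -0.037. The gap between the libraries sorted as tdT-negative was also found outside MyoFB, at 3.82-fold in AdvFB, 3.44-fold in DivFB-G2M, 2.75-fold in MatFB-Im,Cuff, 3.27-fold in MatFB-Type 1 and 3.32-fold in MatFB-Type 2 for Cdk8, but with 1 library per gate, a property of the GFP-high tdT-negative library and one of its cells cannot be told apart for these genes.

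Acta2 was 1485 CPM in AdvFB cells of the GFP-low tdT-negative library and 35.0 CPM in those of the GFP-high tdT-negative library. Doublets are argued against, because the upper quartile of GFP-low AdvFB cells by Acta2 held 0.991 times the median UMIs of the others (95% interval 0.851 to 1.16). The 55 cells of the separate cluster held a median of 23010 UMIs, against 25304 in the other 93. No deposited GFP-low cell held more than 7476 genes and no cell of any library more than 7499. Larger doublets may thus have been filtered out before deposit, which weakens this test. Free RNA is argued against, because MatFB-Type 2 cells of that library held 3.59% of the Acta2 level of its AdvFB cells. A candidate explanation is a second cell population under the AdvFB name in the GFP-low gate: 39.9% of its AdvFB cells lay in clusters with under 2% of the GFP-high tdT-negative AdvFB cells at a resolution of 1.0, and 40.5% at 2.0. At a resolution of 0.5 the share was 3.38%, so this rests on the finer clusterings, and the prediction had named no resolution. The 55 cells of the separate cluster held 1402 CPM of Myh11, 459 CPM of Dcn and 53.8 CPM of Pdgfra, against 2.94, 3885 and 257 CPM in the other 93.

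Pdgfra and H2BGFP were 8.51-fold and 11.1-fold lower in MyoFB-Ter cells of the GFP-high tdT-high than of the GFP-high tdT-negative library. For a shift along an axis that the GFP-high tdT-negative library also holds, the bound set beforehand against it was met. Its MyoFB-Ter cells in the upper quartile by Hhip had a log2 ratio of Pdgfra of 0.16 over the others (95% interval -0.041 to 0.36). The shift is still left open, a reading chosen after the result was seen, because that quartile dilutes its 5 cells in the separate cluster. Those 5 cells held no Pdgfra or H2BGFP UMIs (3 counts would be 31.2 CPM), with Hhip at 1206 and Lrrc15 at 166 CPM. Whether they came from outside the GFP-high gate is not known. Cells from outside the GFP-high gate stay open: 12.6% of the GFP-high tdT-high MyoFB-Ter cells held an H2BGFP UMI, but GFP protein per cell, which outlasts a transcript, is not in the tables. The 23 GFP-low tdT-negative MyoFB-Ter cells lay in the same cluster as 139 of the 190 tdT-high ones, with Pdgfra at 2.09 and 12.5 CPM. These GFP-low and tdT-high cells differed in other genes, with TDT at 2.09 and 78.2 CPM, Lrrc15 at 25.1 and 191 CPM, and Eln at 3019 and 11952.5 CPM. Other genes went the other way, with Kcnq5 at 1743 and 632 CPM and Hhip at 3097 and 1736 CPM. Acta2, Myh11, Actg2 and Actc1 were also higher in the GFP-low cells. The marker lists named the cluster smooth muscle-like. At a resolution of 1.0 it held 73.2% of the GFP-high tdT-high and 1.65% of the GFP-high tdT-negative MyoFB-Ter cells. At 2.0 the counts were 138 of 190 and 5 of 303 cells. A second population under the MyoFB-Ter name is thus a candidate too, but no prediction was written for it and it was not tested. Outside the cluster Pdgfra was lower in the tdT-high library as well, at 59.9 against 213 CPM. The Fgf18-CreERT2 label, the biological explanation that the gates offer, was not tested for Pdgfra and H2BGFP.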

How the results depend on the processing

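The alternatives restricted to cells with Y-linked or with Xist UMIs, the matched type make-up and the types inside or without a separate cluster were chosen after the data were seen. The comparisons called the first, the second and the third are GFP-high tdT-negative over GFP-low tdT-negative, GFP-high tdT-high over GFP-high tdT-negative, and GFP-high tdT-high over GFP-low tdT-negative. Where the counting interval of the main value excluded a ratio of 1, the sign changed in 22 of 1165 gene ratios recomputed in all cells or a shared type, in 41 of 923 list medians and in 36 of 1415 gene ratios within types, the totals counting every value. Without such a change of sign, 605 of the 1165 gene ratios, 269 of the 923 list medians and 431 of the 1415 ratios within types moved. Moved means that the value left the counting interval of the main value. So did 12 of 48 shares of cells in type families. All 54 shares of cells with a UMI moved, where all UMIs or at least 2 UMIs replaced 1 thinned UMI. Of the counts of genes, 61 of 78 stayed within 1.5 times the main count. No paired analysis was possible because each gate has 1 library. Removal of doublets gave no value, since Scrublet marked 4 of 6142 cells and so did not work, and removal of non-mesenchymal classes gave none, since the annotation names none. The shared type of the third comparison, MyoFB-Ter, gave none either, with 23 cells in the smaller library. Depth limits genes near a count of 0. Except where stated, the cause was not tested.

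With TMM, the median of myofibroblast markers was 1.50 in the first and 2.41 in the third comparison, and that of alveolar fibroblast markers -4.06 in the first. With DESeq2 size factors these were 1.50, 2.40 and -4.06. The fibrillar and associated collagens turned to -0.046 with TMM and -0.047 with DESeq2 in the first, and immediate early and dissociation response genes to -0.012 and -0.023 in the third. With the mean of each cell's CPM, myofibroblast markers were at 1.76 in the first and 2.65 in the third comparison, alveolar fibroblast markers at -3.99 in the first, adventitial fibroblast markers at -2.09 and G2 and M phase genes at -0.76 in the second, and Hhip at 0.067 in the third. A pseudocount of 5 gave alveolar fibroblast markers -3.69, -0.88 and -4.47 in the 3 comparisons, adventitial fibroblast markers -1.92 and G2 and M phase genes -0.65 in the second, and myofibroblast markers 2.32 in the third, since it draws low values together.

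A minimum of 10 CPM gave 793 higher and 639 lower genes in the first, 69 and 155 in the second, and 804 and 774 in the third comparison; with no minimum they were 877 and 676, 76 and 157, and 924 and 820, since more genes were counted. Without DivFB cells, alveolar fibroblast markers were at -3.88 in the first, myofibroblast markers at 2.56 in the third and G2 and M phase genes at -0.16 in the second comparison. On thinned UMIs, myofibroblast markers were at 1.71 in the first and 2.60 in the third, alveolar fibroblast markers at -0.85, adventitial fibroblast markers at -2.02 and G2 and M phase genes at -0.73 in the second, Hhip at 0.11 in the third comparison, and apoptosis and p53 targets at 0.0095 and Vsnl1 in MatFB-Im,Cuff at -0.48 in the first.

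Among cells with Y-linked UMIs, myofibroblast markers were at 1.71 in the first and 2.44 in the third comparison, adventitial fibroblast markers at -2.35 and G2 and M phase genes at -0.80 in the second, Hhip at 0.034 in the third, and the fibrillar and associated collagens at -0.047, Cpm in AdvFB at 0.20 and Hhip in AdvFB at -0.017 in the first. Among cells with Xist UMIs, alveolar fibroblast markers were at -3.63 in the first and -5.22 in the third, myofibroblast markers at 2.41 in the third, and in the second 106 genes were lower, adventitial fibroblast markers were at -2.71, immune markers at 0.19, erythroid markers at 0.11, Tagln at 0.099, Kcnq5 in MyoFB-Int at -0.097, Plin2 in MyoFB-IMR at 0.088, and Acta2 and Dcn in MyoFB-Ter at 0.13 and 0.14. There retinoid metabolism was at 0.0079 in the first, and G2 and M phase genes at -0.30 and apoptosis and p53 targets at 0.0077 in the third.

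With matched type make-up, the second comparison had 1 lower gene, alveolar fibroblast markers at -0.033, adventitial fibroblast markers at -0.038, G2 and M phase genes at -0.21, Lum at 0.080, Itm2a at 0.32 and Wnt2 at 0.24. Medians that turned were those of myofibroblast markers (-0.088), endothelial markers (0.027), elastic fibre genes (0.40), fibrillar and associated collagens (0.31), basement membrane (0.034), retinoid metabolism (0.0041), the PDGF and IGF pathway (0.26) and the immediate early and dissociation response (0.14). Within MyoFB-Int it had 15 lower genes, 2 of them among the main 59, with alveolar fibroblast markers at -0.13, adventitial fibroblast markers at -0.39, G2 and M phase genes at -0.26, Itm2a at 0.39 and Tcf21 at 0.27. There myofibroblast markers turned to -0.046, smooth muscle markers to -0.054, pericyte markers to 0.058, elastic fibre genes to 0.40, fibrillar and associated collagens to 0.27, retinoid metabolism to 0.032, FGF ligands, receptors and targets to 0.0098, the PDGF and IGF pathway to 0.28 and the immediate early and dissociation response to 0.18. Within AdvFB the first comparison had 120 higher genes, 27 of them shared with the main count, and 155 lower, 28 of them shared. There myofibroblast markers were at -0.33, alveolar fibroblast markers at 0.20, the contractile apparatus at -1.64, smooth muscle markers at -4.12, pericyte markers at -1.09, basement membrane at 0.0062, lipid storage and lipoprotein handling at 0.16, retinoid metabolism at 0.17, the hedgehog pathway at 0.23, the TGF-beta and BMP pathway at -0.28, vascular ligands and guidance at 0.41, S phase genes at -0.13, the immediate early and dissociation response at -0.036, Zfp536 at -0.16, Nes at -0.85, Htra1 at -0.17, Trim67 at -0.47, Ccdc3 at -1.42, TDT at -0.38, Acta2 at -5.37, Tagln at -5.33, Prkg2 at 0.12, Wnt2 at 0.63, Scube2 at 0.13, Plin2 at 0.20 and Hhip at 0.22. Without the separate cluster, Erbb4 in AdvFB was at 1.01, Hhip at -0.16, Htra1 at 0.33 and Nes at 0.25 in the first comparison, and Kcnq5 in MyoFB-Ter at -3.38 and Dcn at 0.20 in the second. The Kcnq5 value rests on 0 UMIs in 51 GFP-high tdT-high cells, which allows up to 3.05 CPM, so the size of its fall is not known.

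MatFB-Im,Cuff was divided by its cluster 14 in the first comparison, because most of its cells lay in different clusters in the 2 libraries. Without that cluster, with 17 and 187 cells, Eln in MatFB-Im,Cuff was at -0.999, Hhip at -2.12, Lrrc7 at -1.50, Unc5d at -0.83, Trim67 at -0.60, Fgf18 at -0.33, Trpc6 at -0.33 and Nes at -0.0046. Inside it, with 93 and 18 cells, Slc7a10 was at 3.31, Hsd11b1 at 2.67, Prkg2 at 2.52, Nav2 at 2.31, Ctnnd2 at 1.86, Nebl at 1.72, Wnt2 at 1.13, Tagln at 0.81, Scube2 at 0.62, Slc27a6 at 0.58, Npnt at 0.39, Cpm at 0.32, Plin2 at 0.13, Ces1d at 0.099 and Hhip at -0.63. The 17 cells held no UMI of Lrrc7, Unc5d, Trim67, Fgf18 or Trpc6, which allows up to 7.76 CPM, and the 18 cells none of Slc7a10, Prkg2 or Wnt2, which allows up to 8.11 CPM, so these signs rest on few cells. Of the 17 cells, 10 lay in an adventitial fibroblast-like cluster that held 0 GFP-low cells of the type.

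Clusters named by marker lists gave other shares, in part because clusters of MyoFB-Ter and AdvFB cells took smooth muscle names. At resolution 1.0, clusters with myofibroblast names held 3.04% of GFP-low and 87.8% of GFP-high tdT-high cells, and those with adventitial fibroblast names 6.93% of GFP-low cells. At 2.0, clusters with myofibroblast names held 2.73%, 66.4% and 81.1% of the 3 libraries and those with adventitial fibroblast names 6.85% of GFP-low cells. There 455 of 2659 GFP-high tdT-negative and 99 of 1458 GFP-high tdT-high MyoFB cells took pericyte names, and 5 and 138 took smooth muscle names. At 1.0 with Pdgfra, Fgf18, H2BGFP, TDT and CreERT2 kept, clusters with myofibroblast names held 3.04% of GFP-low and 87.8% of GFP-high tdT-high cells. Those with alveolar fibroblast names held 2.03% of GFP-high tdT-negative cells, and those with adventitial fibroblast names 8.41% of GFP-low and 12.8% of GFP-high tdT-negative cells. Of the latter, 1 cluster with 107 GFP-high tdT-negative and 21 GFP-low cells was 89.9% MatFB-Im,Cuff cells, so these shares are not shares of AdvFB cells.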

Other observations

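Within the GFP-high tdT-negative library, MyoFB-IMR, MyoFB-Int and MyoFB-Ter cells formed an order in several genes. Pdgfra stood at 699, 390 and 209 CPM in these types and H2BGFP at 340, 177 and 83.4 CPM, while Fgf18 stood at 35.0, 70.4 and 124 CPM, Eln at 3239, 7131 and 10556 CPM and Aspn at 8.59, 268 and 1708 CPM. In the GFP-high tdT-high library Pdgfra and Fgf18 had the same order, and Eln was highest in MyoFB-Int, at 15714 CPM. The separate cluster of MyoFB-Ter cells differed between gates in Actc1, a cardiac actin gene, which stood at 2014 CPM in 23 GFP-low tdT-negative cells and 16.3 CPM in 139 GFP-high tdT-high cells.

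MatFB types of the GFP-low tdT-negative library differed in sex-linked transcripts. Of MatFB-Type 1 cells, 191 of 199 (96.0%, 95% interval 92.2 to 98.2) held Y-linked but no Xist UMIs, against 248 of 651 MatFB-Type 2 cells (38.1%, 34.3 to 41.9) and 83 of 205 MatFB-Im,Cuff cells (40.5%, 33.7 to 47.5).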
